A study of Mus musculus with 1152 samples.

How the data were processed

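RNA of single T helper cells from house dust mite (HDM) exposed mice was measured by Smart-seq2, a full-length single-cell RNA sequencing method without molecular identifiers. Each of 3 plates held 384 wells, and each well is 1 sample. The plates labelled bronchoalveolar lavage (BAL) at day 15 came from mouse 1 and mouse 2, so the mouse was the replicate and cells were not counted as replicates. The plate of day 10 carried labels that name both lymph node and lung. The design text lists 764 memory T helper cells (CD44 positive) from 2 mice at day 15. Beside them it lists 50 naive and 50 regulatory T cells from the mediastinal lymph node of a mouse without allergen, and ST2-positive cells at day 10, 200 from lymph node and 82 from lung, or 382 cells in all. Which well held which of these sorts is not in the labels, so no well of this plate was assigned to a sort.

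The authors deposited RPKM values (reads scaled by gene length and by the reads of the well), with 24490 entries per well and overlapping genes joined under 1 name. The submitters' notes name TopHat and Cufflinks and the builds mm9 and mm10, and the sample titles name star and mm10; versions and the role of each are not given in the sources used here. Gene names with more than 1 entry (279 names, 771 entries) were left out, and 4 gene list symbols were found under older symbols. Positions are from the GENCODE vM21 annotation of GRCm38.

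No read counts were used as the main unit. The RPKM values of a gene lay on whole-number steps, from which the number of reads behind each value and the reads by which each well was scaled were recovered. Steps were recovered for 11262 genes, which hold 81.6%, 81.0% and 81.0% of the nonzero values of BAL mouse 1, BAL mouse 2 and the day 10 plate. Of these values, 99.5%, 99.1% and 99.1% were whole within 0.02 reads. The scale was fixed by 1395 genes whose lengths matched the annotation's exon unions. On simulated data of 120 wells and 8000 genes, 100% of the nonzero values with a recovered step were returned within 0.02 reads. Values without a step were not counted, and the scale from gene lengths was not part of this check.

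Wells with at least 50000 reads and 1000 genes were kept, 320 of BAL mouse 1, 367 of BAL mouse 2 and 358 of the day 10 plate; 64, 17 and 26 wells were left out. Kept wells held 50080 to 547342 reads in mouse 1, 71672 to 475556 in mouse 2 and 70029 to 736096 on the day 10 plate. Median reads were 115174, 337734 and 318791. Sequencing reads here are not independent molecules, so intervals and limits cover counting error only.

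Kept cells of the 3 plates were clustered together on log2(RPKM + 1) of a panel of 70 marker genes alone (15 principal components, 15 neighbours, Leiden resolution 1.0, no plate correction), which gave 12 clusters. A cluster took a class name when the mean z-score of the class's markers reached 0.5 and at least 3 of them were detected in at least 10 percentage points more cells than elsewhere. Where the markers of more than 1 T cell class passed, the name was compound. The 10 leading genes of each cluster, among genes detected in at least 20% of its cells, were looked at beside the name; a cluster that passed stayed unnamed where more of them were markers of another class than of its own. This did not change a name in the clustering used, but 5 clusters of the alternatives lost the name Treg-like to it (97 cells with the 2000 most variable genes, 34 and 54 with each plate clustered on its own, 64 with the deeper wells and 84 without the interferon markers). This naming rule was set after the values had been seen and was adjusted after the clusters had been seen. Clusters whose markers did not pass were called unnamed, and a cluster with myeloid markers was left out of the T cell classes. No caller of doublets was run.

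For each class and mouse the mean RPKM over cells was taken, and log2(mean RPKM + 1) was fitted with limma (limma-trend) with class and mouse as terms. The mouse was a block because all classes of a mouse came from the same animal and plate. Over the 10 pairs of classes, the mouse differences of 9463 genes had a median Pearson r across genes of 0.175 (0.108 to 0.241), and genes are not independent replicates. Classes needed at least 10 cells in both mice, which gave 5 classes and 10 means, with 4 residual degrees of freedom and 6.3 prior degrees of freedom. Each class was compared with the equally weighted mean of the other 4. Genes needed a mean RPKM of at least 5 in 2 of the means, and marker panel genes were not counted among the calls. The 3 class comparisons come from this fit and share its means, so they are not independent. The Th2-like cells of BAL were compared with the Th2-like cells of the day 10 plate by limma on 2 mice against 1 plate, with 1 residual degree of freedom and 385.4 prior degrees of freedom; the lone plate was assumed to vary like the mice. That test was set against 50 draws in which 13 Th2-like cells of 1 BAL mouse stood in for the plate; since these gave a median of 1194 calls, its p-values were not used as evidence. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All p-values of the class comparisons rest on 2 mice.

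The well minimum, marker panel, comparisons, 13 gene lists, rule for named genes and most alternatives were chosen before the data were examined. The tests were written for counts with limma on RPKM as the substitute, and the clustering and the gene rule were moved from CPM to RPKM in the same way. Named genes had an absolute log2 fold change of at least 1, a mean log2 value of at least 4, an adjusted p under the threshold and the same sign in both mice. Up to 12 genes per direction were named for the Th2-like class, 6 for the Treg-like and Th1-like classes and 10 for BAL against day 10, by size of change. Predicted gene models and receptor segments were not named; clone names starting with AW or BC, Mir and Snor genes and joined names were also left out, which the written rule does not say. Within the day 10 plate, the 8 genes with the largest fold were named among genes with a mean RPKM of at least 50 in either group. Members of the gene lists could be named with their values.

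The lists were Th2 cytokines and effectors, Th2 receptors and transcription factors, lipid uptake and oxidation, glycolysis, oxidative phosphorylation, interferon-stimulated genes, cytotoxic and Th1-associated genes, Treg-associated genes, tissue residency and egress, co-inhibitory receptors, immediate early genes, cell cycle genes and antigen-presenting cell genes. Members were counted as past the threshold over all genes tested and adjusted over the list alone. Each list was also tested against all other genes with camera at a preset inter-gene correlation of 0.01 and at an estimated correlation, 52 tests over 4 comparisons. Of these, 19 passed with the preset correlation, 5 of them in the comparison with day 10, which were not used as evidence, and 3 with the estimated one.

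The limma test was checked on data simulated from its fitted means and moderated standard deviations, with 200 genes changed. It found 8.8% of Th2-like changes of 1 on the log2 scale, 39.4% of changes of 2 and 92.4% of changes of 4, and called 5 unchanged genes. For the Treg-like class these values were 5.9%, 57.6% and 89.4% with 6 unchanged genes, and for the Th1-like class 10.3%, 40.9% and 90.9% with 9. For BAL against day 10 they were 2.9%, 24.2% and 90.9% with 3. Since the spread of this check is that of the fit itself, few unchanged genes were to be found in it, and for day 10 the median of 1194 calls with stand-in cells shows that the spread was too small. An earlier version with each gene's own standard deviation found fewer, and the moderated one was chosen after that was seen.

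Shares of cells have exact Clopper-Pearson 95% intervals. Alternatives were another scaling (median ratios), a pseudocount of 0.1, no filter on low values, wells of at least 100000 reads and 1500 genes, cells thinned to 50000 reads (seed 7), resolutions of 0.6 and 1.6, clusters from the 2000 most variable genes, each plate clustered on its own, no replicate block, the other cells pooled, and each mouse left out. Added after the data were seen were recovered reads summed over cells, wells in another order, cells with a read of 8 myeloid genes left out, and equal numbers of Th2-like cells per mouse and plate (50 draws of 13). The Treg-like gene lists were also tested with clusters from the 62 panel genes that are not interferon markers, named with and without the rule on leading genes, and the stand-in draws with median-ratio scaling and a pseudocount of 0.1. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and the package data.table, version 1.17.8.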

Results

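T helper cells drive the airway inflammation that follows inhaled HDM, and the series asks which states these cells take in the airways and how they relate to cells of the draining lymph node and lung. Single cells were sorted from BAL of 2 mice at day 15 (384 wells each) and onto a further plate of 384 wells at day 10. Median depth over all wells was 104709 reads in BAL mouse 1, 333046 in BAL mouse 2 and 306632 on the day 10 plate. Kept cells had a median of 2046, 2556 and 2367 detected genes.

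The T helper cells of BAL fell mainly into Treg-like, Th2-like, Th1-like and Tfh-like classes. The Tfh-like class was smaller in each of 8 other clusterings and held 0 BAL cells with each plate clustered on its own. In 2 of the 8 no Th1-like class formed, and in 2 a Th17-like class did. Gata3, the regulator of type 2 differentiation, was detected in 93.7% and 98.9% of the cells of the 2 Th2-like clusters, and in 75.2% and 74.1% of the cells outside each. Il1rl1, which encodes the interleukin-33 receptor ST2, was detected in 90.5% and 93.5% against 42.9% and 41.1%, and Il13 in 30.2% and 35.5% against 4.6% and 3.3%. The Treg-like clusters held Foxp3, the regulator of Treg identity, in 93.0% and 89.9% of cells against 35.4% and 39.9%. Th1-like cells carried the chemokine receptor gene Cxcr3 in 92.6% against 28.2% and Tbx21, which encodes T-bet, in 23.1% against 5.5%. In Tfh-like cells Pdcd1 was detected in 70.3% against 31.1% and Cxcr5 in 25.4% against 14.1%. These percentages cover the kept cells of all 3 plates, which were clustered together, and not those of BAL alone. The genes belong to the marker panel and so define the classes.

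Treg-like cells were 24.4% of the kept cells of mouse 1 (78 of 320 cells, exact 95% interval 19.8% to 29.5%) and 29.2% of mouse 2 (107 of 367, 24.6% to 34.1%). Th2-like cells were 21.6% (69 cells, 17.2% to 26.5%) and 20.2% (74 cells, 16.2% to 24.6%). Th1-like cells were 17.2% (55 cells, 13.2% to 21.8%) and 13.9% (51 cells, 10.5% to 17.9%). Tfh-like cells were 14.1% (45 cells, 10.5% to 18.4%) and 12.8% (47 cells, 9.56% to 16.7%), but 0.0% to 7.43% and 0.0% to 8.17% over the 8 other clusterings. Cells led by interferon-stimulated genes were 2.5% of mouse 1 (8 cells, 1.09% to 4.87%) and 11.7% of mouse 2 (43 cells, 8.61% to 15.5%), and these intervals did not overlap. Naive or central memory cells were 2.19% and 1.91%, with 7 cells in each mouse, but 13.8% (44 cells) and 16.9% (62 cells) with each plate clustered on its own. Unnamed cells were 11.9% (38 cells) and 7.63% (28 cells), and 15.9% to 42.8% and 12.5% to 50.4% over the 8 other clusterings. The Th17-like class held 25 cells of mouse 1 (7.81%) and 0 of mouse 2 with each plate on its own, and 6.25% and 5.18% without the interferon markers. Compound Treg and interferon cells were 0.62% and 2.18%, and compound Treg and naive cells 0.31% and 0.27%. The mice were 1 value each, so shares were not tested between them. With wells of at least 100000 reads and 1500 genes, the Th2-like share was 10.9% in mouse 1 and 12.8% in mouse 2. Clusters from the 2000 most variable genes gave 28.1% (23.3% to 33.4%) and 13.6% (10.3% to 17.6%), intervals that did not overlap.

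**Figure D1:**
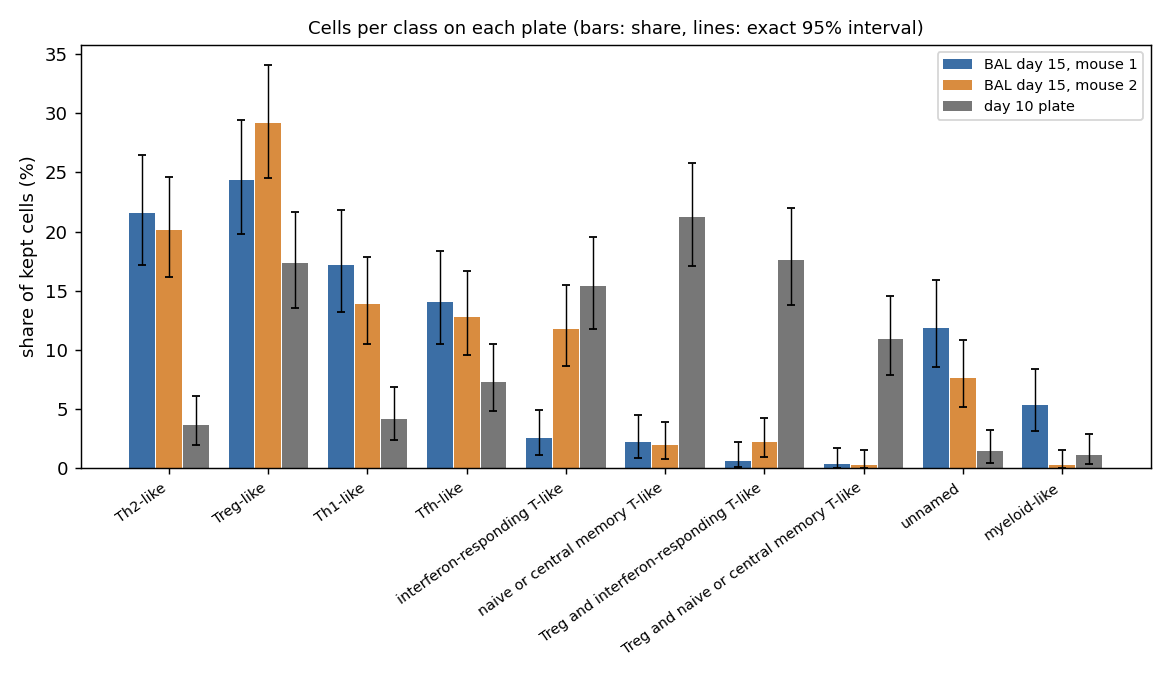
Share of kept cells (percent, vertical axis) in each class (horizontal axis) for BAL mouse 1, BAL mouse 2 and the day 10 plate; bars are shares and lines are exact 95% binomial intervals. Th2-like cells were 21.6% and 20.2% of the cells of the BAL mice and 3.63% of the day 10 plate. The sorts that the design lists set the make-up of that plate, so its shares are no tissue frequencies to set against BAL.

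The first comparison asks what sets Th2-like cells of the airways apart from the other T helper classes there. Plac8, a small cysteine-rich protein of leukocytes, rose by 3.54 ± 0.26 (log2 fold change, SE, 2 mice; limma adjusted p = 0.00025), to mean RPKM values of 1511 and 1168 in mice 1 and 2. Ltb4r1, the receptor of the chemoattractant leukotriene B4, rose by 2.59 ± 0.35 (adjusted p = 0.0145), and the chemokine receptor gene Cxcr6 by 1.36 ± 0.18 (adjusted p = 0.0145). The GTPase gene Gimap4, from a family tied to lymphocyte survival, fell by 1.92 ± 0.13 (adjusted p = 0.000228), and its relative Gimap3 fell by 1.45 ± 0.15 (adjusted p = 0.00336). Of a pair of membrane channel genes, Tmem176b fell by 3.31 ± 0.25 (adjusted p = 0.000261) and Tmem176a fell by 3.73 ± 0.42 (adjusted p = 0.00491; -4.61 in mouse 1 and -2.84 in mouse 2). The unnamed class is part of the reference and was high in both genes against the other classes. In mice 1 and 2 it was at 3.38 and 2.46 for Tmem176b and at 3.77 and 2.39 for Tmem176a. How far these 2 falls reflect a raised reference was not tested.

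Other genes that rose were Fgl2, a secreted fibrinogen-like protein (2.48 ± 0.33, adjusted p = 0.0145), Gclc, the catalytic subunit of the first enzyme of glutathione synthesis (2.45 ± 0.37, adjusted p = 0.0288), and Nfkb1, an NF-kappa-B subunit (1.66 ± 0.22, adjusted p = 0.0145). Fgl2 was low in the unnamed class of the reference, at -2.93 and -2.27 against the other classes in mice 1 and 2. Rgs1, which dampens chemokine receptor signals, rose by 1.17 ± 0.16 (adjusted p = 0.0145), and Ctla2a by 1.25 ± 0.20 (adjusted p = 0.0326). Slamf6, a receptor of the SLAM family, fell by 3.06 ± 0.31 (adjusted p = 0.00336), with -2.45 in mouse 1 and -3.66 in mouse 2. Trat1, an adaptor of the T cell receptor, fell by 3.82 ± 0.41 (adjusted p = 0.00336), with -4.42 in mouse 1 and -3.22 in mouse 2. Gramd3 fell by 4.02 ± 0.54 (adjusted p = 0.0145). Ms4a4b, a tetraspan protein of T cells, fell by 1.31 ± 0.19 (adjusted p = 0.0176). The actin-binding protein gene Lsp1 fell by 1.03 ± 0.14 (adjusted p = 0.0145). On GRCm38, Gimap4 (48684549 to 48692060), Gimap3 (48764464 to 48770851), Tmem176b (48833818 to 48841496) and Tmem176a (48840919 to 48847071) lie close together on chromosome 6, and the last 2 overlap on opposite strands. Plac8 lies on chromosome 5, from 100553725 to 100572245.

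In all, 9 genes rose and 11 fell among 9463 tested (limma, Benjamini-Hochberg), each with the same sign in both mice. At an unadjusted p under 0.05 there were 599 genes. The 3 calls outside the rule for named genes, named after their values were seen, were Tagln2 (0.95), Gimap6 (-0.89) and AW112010 (-0.67). Over 14 other settings the counts ran from 1 to 37 higher and from 3 to 34 lower. All 17 named genes kept their sign in these settings; Gimap4 passed in 14, Plac8 and Tmem176b in 13, Cxcr6 and Gclc in 5 and Ctla2a in 1.

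Among the gene lists, 1 of 7 measured Th2 cytokines and effectors rose over all genes (Plac8) and 5 rose adjusted over the list alone, and the list as a whole rose (camera adjusted p = 1.2e-10; adjusted p = 0.0281 with an estimated correlation). Its members included Igfbp7, an insulin-like growth factor binding protein (3.19, adjusted p = 0.0673), and Il6 (4.45, adjusted p = 0.115). Reads of Il6 were found in only 9 of 69 and 6 of 74 Th2-like cells of mice 1 and 2. Those of Igfbp7 were found in 44 and 39 of these cells. Of 18 Th2 receptors and transcription factors, 1 rose over all genes (Ltb4r1) and 8 adjusted over the list alone, among them Cd200r1 (2.42, adjusted p = 0.0539 over all genes), Epas1 (3.27, adjusted p = 0.0608) and the lipid-sensing nuclear receptor Pparg (2.93, adjusted p = 0.0902). That list rose with the preset correlation (camera adjusted p = 1.76e-07; adjusted p = 0.116 with an estimated correlation). The study itself discusses Igfbp7, Plac8, Il6, Cd200r1, Pparg and Bhlhe41, so these 2 lists are not independent evidence. The class was also formed on Th2 markers of the panel, so a rise of other Th2 genes was to be found.

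Of 13 residency and egress genes, Cxcr6 and Rgs1 rose, 5 rose adjusted over the list alone and 7 were positive. The list passed with the preset correlation (camera adjusted p = 0.0379; adjusted p = 0.166 with an estimated correlation), with a median log2 fold change of 0.115 against 0.095 for all genes. The 27 lipid genes rose as a list (median log2 fold change 0.49, camera adjusted p = 0.017; adjusted p = 0.154 with an estimated correlation) with 0 members past the limma threshold. Glycolysis rose as a list (13 genes, 0 past the threshold and 1 adjusted over the list alone, Ldha at 0.78; camera adjusted p = 0.0478; adjusted p = 0.166 with an estimated correlation). Immediate early genes did so too (13 genes, 0 past the threshold, Egr2 3.33 and Egr3 3.32; camera adjusted p = 0.0132; adjusted p = 0.285 with an estimated correlation). The 6 co-inhibitory receptors fell as a list (0 past the threshold and 2 lower adjusted over the list alone, Tigit -0.96 and Vsir -1.14; camera adjusted p = 0.00373; adjusted p = 0.116 with an estimated correlation). Oxidative phosphorylation did not pass (29 genes, adjusted p = 0.0758), nor did cytotoxic and Th1-associated genes (17 genes, 1 higher, Cxcr6; adjusted p = 0.0758) or interferon-stimulated genes (32 genes, 0 called, adjusted p = 0.344). Among Treg-associated genes 0 were called (19 genes, 5 higher and 1 lower adjusted over the list alone; adjusted p = 0.343), and the list did not pass. Cell cycle (18 genes) and antigen-presenting cell genes (5 genes) did not pass either (adjusted p = 0.927 each). Reads of 8 myeloid genes were found in 18.8% and 6.8% of the Th2-like cells of mice 1 and 2, against 21.5% and 6.6% of all T cells. Median, mean and test differed in sign for antigen-presenting cell genes in the Th2-like and Treg-like comparisons and for interferon-stimulated genes in the Th2-like one. They also did so for Th2 cytokines in the Treg-like comparison; none of these tests passed.

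Treg-like cells of BAL were compared in the same way, to ask what marks airway Treg cells. Tigit, a co-inhibitory receptor, rose by 2.70 ± 0.21 (log2 fold change, SE, 2 mice; limma adjusted p = 0.000933). Itgae, the CD103 integrin chain, rose by 3.004 ± 0.38 (adjusted p = 0.0074), and Klrg1, a receptor of terminally differentiated cells, by 6.18 ± 1.03 (adjusted p = 0.0288). The serine protease gene Gzmb rose by 6.78 ± 0.82 (limma adjusted p = 0.0074) and Il10, an anti-inflammatory cytokine, by 4.60 ± 0.57 (adjusted p = 0.0074). These 2 are given as members of the gene lists. Their mean log2 value was under the minimum of 4 for named genes, and they were not followed over the other settings. The anti-apoptotic gene Bcl2 fell by 3.40 ± 0.43 (adjusted p = 0.0074), and the copine gene Cpne7 fell by 4.96 ± 0.43 (adjusted p = 0.000933; -5.78 in mouse 1 and -4.15 in mouse 2).

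The chemokine receptor gene Ccr1 rose by 2.61 ± 0.45 (adjusted p = 0.0346), Ncmap by 2.41 ± 0.30 (adjusted p = 0.0074) and the interferon-induced GTPase gene Gbp3 by 3.56 ± 0.62 (adjusted p = 0.0354). The semaphorin gene Sema4a fell by 3.53 ± 0.56 (adjusted p = 0.02; -4.41 in mouse 1 and -2.65 in mouse 2), and Tbc1d4, a Rab GTPase activator, fell by 2.72 ± 0.39 (adjusted p = 0.0128). Ehd3 fell by 3.01 ± 0.43 (adjusted p = 0.0122), with -2.05 in mouse 1 and -3.97 in mouse 2. The inhibitory receptor gene Btla fell by 3.05 ± 0.54 (adjusted p = 0.0354), with -4.25 in mouse 1 and -1.85 in mouse 2. In all, 38 genes rose and 27 fell among 9463 tested by limma, and 762 had an unadjusted p under 0.05. The counts ran from 0 to 42 higher and from 0 to 30 lower over 14 other settings, in which the 12 named genes kept their sign. Tigit passed in 13 of these settings, Itgae in 10, Cpne7 and Bcl2 in 9, and Btla in 3.

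Of 19 Treg-associated genes, 8 rose over all genes and 14 adjusted over the list alone, where 1 fell (Nrp1, -0.71), and the list rose (camera adjusted p = 5.92e-22; adjusted p = 0.0213 with an estimated correlation). Tnfrsf9 (4.22), Tnfrsf18 (1.48) and Tnfrsf4 (1.68), costimulatory receptors of the TNF family, were among those that rose. The class was formed on Treg markers of the panel, so a rise of other Treg-associated genes was to be found. This list thus describes the class and is no independent evidence. Of 32 interferon-stimulated genes, 4 rose (Gbp3, Gbp7, Ly6a and Ifi27l2a), 9 rose adjusted over the list alone and 29 had positive values; the list rose (camera adjusted p = 4.8e-13; adjusted p = 0.0213 with an estimated correlation). The clustering used interferon markers and so set aside 51 interferon-responding cells and 10 compound Treg and interferon cells of BAL. Clustered without these markers, 0 of 33 listed genes were called by limma over all genes (883 of 9364 genes had an unadjusted p under 0.05), and 29 were positive. The list then had adjusted p = 7.31e-09, and adjusted p = 0.185 with an estimated correlation. In that clustering 84 cells with Treg markers stayed unnamed, 25 of BAL mouse 1 and 46 of BAL mouse 2 among them, and those of BAL were among the cells compared against. Named Treg-like instead, they gave 2 called genes, Gbp3 (2.20, adjusted p = 0.0423) and Ly6a (1.355, adjusted p = 0.0423), and the list had adjusted p = 3.19e-07, and adjusted p = 0.236 with an estimated correlation. Over the 32 genes measured in each, the median log2 fold change was 0.87 (quartiles 0.54 and 1.08) in the clustering used, 0.61 (0.36 and 1.00) under the first naming and 0.71 (0.20 and 0.92) under the second. The estimated correlation between genes was 0.028, 0.105 and 0.179, so the p with an estimated correlation rests on this as well as on the fold. Gbp3 was at 3.56 (SE 0.62) in the clustering used and at 1.80 (SE 0.34, adjusted p = 0.0959) under the first naming, and it passed in 4 of the 14 other settings. The remaining 11 lists did not pass. They included cytotoxic genes (17 genes, 3 higher, Gzmb, Ccr2 and Il2rb; adjusted p = 0.409), Th2 cytokines (7 genes, Il10 higher and Plac8 lower at -1.88; adjusted p = 0.354) and Th2 receptors (18 genes, Icos higher at 1.15 and Il7r lower at -1.32; adjusted p = 0.409). Residency genes (13 genes, Itgae higher and Itgb1 lower at -1.74; adjusted p = 0.588) and co-inhibitory receptors (6 genes, Tigit higher and Btla lower; adjusted p = 0.273) were among them too. With 0 genes called, the others were oxidative phosphorylation (adjusted p = 0.0781), lipid genes, glycolysis and immediate early genes (adjusted p = 0.684 each), cell cycle (adjusted p = 0.409) and antigen-presenting cell genes (adjusted p = 0.354). Reads of the myeloid genes were found in 17.9% and 7.5% of Treg-like cells. Without the cells that had such reads, 17 genes fell instead of 27.

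Th1-like cells of BAL carried more Ms4a4b and Gimap transcripts and less Ccr1 and Il10 than the other classes. Ms4a4b rose by 1.69 ± 0.19, Gimap6 by 1.25 ± 0.14 and Gimap4 by 1.16 ± 0.13 (log2 fold change, SE, 2 mice; limma adjusted p = 0.00549 each). Ccr1 fell by 5.34 ± 0.45 (adjusted p = 0.00238), and Ramp1, a partner of the receptor of the neuropeptide CGRP, fell by 3.06 ± 0.34 (adjusted p = 0.00549). Angptl2, a secreted angiopoietin-like protein, fell by 3.13 ± 0.35 (adjusted p = 0.00549). Ncmap fell by 2.63 ± 0.30 (adjusted p = 0.00576), and the actin-capping gene Capg fell by 1.33 ± 0.17 (adjusted p = 0.0154). The glutaredoxin gene Glrx fell by 1.83 ± 0.28 (adjusted p = 0.0457). Gimap4 and Ms4a4b thus fell in the Th2-like and rose in the Th1-like comparison. Each of these classes is part of the other's reference, and no Th1-like against Th2-like difference was tested alone. Ccr1, Ncmap and Il10 likewise rose in the Treg-like comparison, and the Treg-like class is part of the Th1-like reference.

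In all, 5 genes rose and 8 fell among 9463 tested by limma, with 832 at an unadjusted p under 0.05. Calls outside the rule for named genes, chosen after their values were seen, included Rpl13a (0.64), Il10 (-4.61) and Tamm41 (-4.11). Over 12 other settings, from 1 to 14 genes were higher and from 2 to 38 lower, and the 9 named genes kept their sign; Ms4a4b passed in 11 and Glrx in 6.

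The 19 Treg-associated genes fell as a list, with 2 lower over all genes (Il10 and Capg), 9 lower adjusted over the list alone and 0 positive (camera adjusted p = 4.94e-14; adjusted p = 0.0577 with an estimated correlation). Th2 receptors and transcription factors fell (18 genes, 0 called; 8 lower and 1 higher adjusted over the list alone; camera adjusted p = 5.21e-05; adjusted p = 0.169 with an estimated correlation). Th2 cytokines fell too (7 genes, Il10 lower, 3 lower adjusted over the list alone; camera adjusted p = 0.00153; adjusted p = 0.148 with an estimated correlation). Both hold genes that the study discusses and are not independent evidence. The Treg-like and Th2-like classes are part of the reference here. Treg-associated genes had a median log2 fold change of 1.68 in the Treg-like comparison. Th2 cytokines were at 1.90 and Th2 receptors at 1.14 in the Th2-like one. How far these 3 falls reflect a raised reference was not tested. The 18 cell cycle genes fell as a list with 0 called (camera adjusted p = 0.000616; adjusted p = 0.28 with an estimated correlation), Mcm5 at -2.82 among them. Cytotoxic and Th1-associated genes rose as a list (17 genes, 0 called; 4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00882; adjusted p = 0.28 with an estimated correlation). Their highest member was the granzyme gene Gzmk (6.58 ± 1.05, limma adjusted p = 0.0501, which did not pass). The class was formed on Th1 markers of the panel, so a rise of this list was to be found and is no independent evidence. The other lists did not pass, with 0 genes called in each. They were interferon-stimulated genes (32 genes, adjusted p = 0.137), co-inhibitory receptors (6 genes, adjusted p = 0.136) and residency genes (13 genes, adjusted p = 0.146). So were glycolysis (13 genes, adjusted p = 0.205), oxidative phosphorylation (29 genes, adjusted p = 0.271) and immediate early genes (13 genes, adjusted p = 0.393). Antigen-presenting cell genes (5 genes, adjusted p = 0.583) and lipid genes (27 genes, adjusted p = 0.702) did not pass either. Reads of the myeloid genes were found in 27.3% and 9.8% of Th1-like cells.

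**Figure D2:**
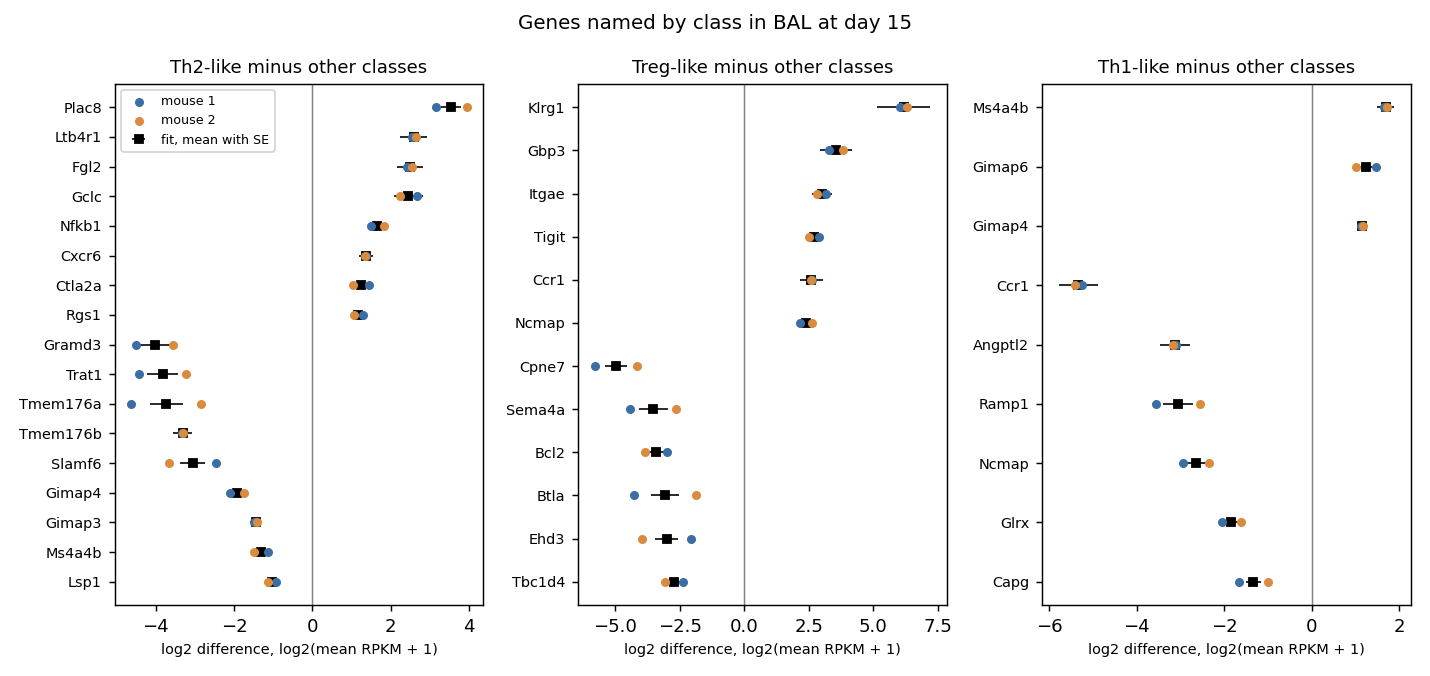
Log2 fold change (horizontal axis) of the named genes (vertical axis) of the Th2-like, Treg-like and Th1-like classes of BAL against the mean of the other classes; dots are mice 1 and 2, and the wider marks with lines are the limma mean and SE. Both mice lie on the same side of 0 for every gene drawn, from Plac8 at 3.15 and 3.94 to Gramd3 at -4.50 and -3.55 in the Th2-like panel.

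Interferon-responding and naive classes were also to be compared, but mouse 1 held 8 and 7 such cells and mouse 2 held 43 and 7, under the minimum of 10 in both mice, so no test was made.

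Th2-like cells of BAL at day 15 were then set against those of the day 10 plate, to ask what airway Th2 cells have that cells of an earlier stage in lymph node and lung lack. Here limma called 1000 genes higher and 310 lower in BAL among 7553 tested, with 2115 at an unadjusted p under 0.05. Over 12 other settings the counts ran from 0 to 1016 higher and from 0 to 306 lower. When 13 Th2-like cells of a BAL mouse stood in for the plate, the same test called a median of 1194 genes (range 0 to 1704), and 19 of 50 draws gave at least 1310 calls. With 13 cells from each mouse, the median against the plate was 2 calls. The calls and p-values of this comparison therefore support no single gene or list, and what follows are values without a test, of genes picked by those calls and by size. Day, organ, plate and sort cannot be separated here.

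**Figure D3:**
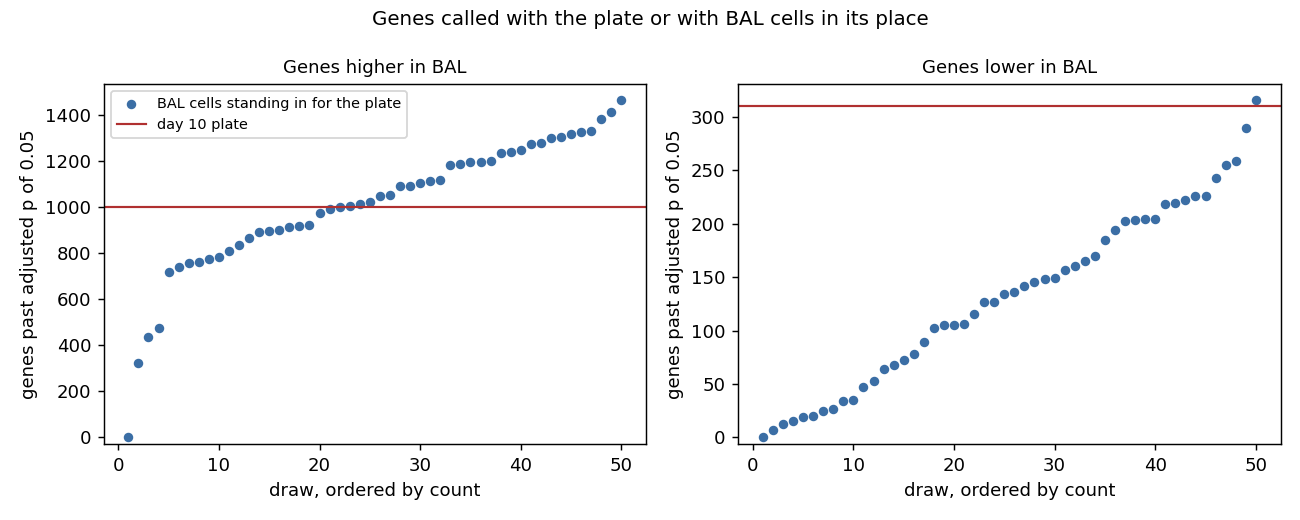
Number of genes called by limma (vertical axis) as higher (left) or lower (right) in BAL in each of 50 draws in which 13 Th2-like BAL cells stood in for the day 10 plate, ordered by count (horizontal axis); red lines are the counts with the plate itself. Of the 50 draws, 28 reach the 1000 higher genes of the plate and 1 reaches its 310 lower genes; with median-ratio scaling 38 and 13 draws reach its 741 higher and 124 lower genes.

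Fgl2 was listed at 0 in the 13 Th2-like cells of the plate and had reads in 61 of 69 and 65 of 74 Th2-like cells of BAL mice 1 and 2. Plac8 had reads in 2 of 13 cells on the plate and in 44 of 69 and 38 of 74 cells of BAL, with a log2 difference of 5.01. For Bhlhe40, a transcription factor of cytokine-producing T cells, the difference was 4.42, for Rgs1 2.12 and for Cxcr6 2.18. Gpr183, a chemotactic receptor for oxysterols, was at -3.28 (-2.52 against mouse 1 and -4.04 against mouse 2), with reads in 8 of 13 plate cells against 15 of 69 and 14 of 74. The transcription factor gene Irf4 was at -3.56 (7 of 13 cells against 8 of 69 and 6 of 74), and the homing receptor gene Gpr15 at -4.52 (4 of 13 against 2 of 69 and 1 of 74).

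Tnfsf11, the cytokine RANKL, the lipid droplet protein gene Plin2, Ctsw, Rnase4, Ctla2b and Pea15a were listed at 0 on the plate, so they have no fold. Atp6ap2 was at 6.37, Igbp1 at 6.28 and Nsmce4a at 5.96. Atp6ap2 had reads in 1 and Igbp1 in 2 of the 13 Th2-like cells of the plate. In the 336 cells of the plate's other named T helper classes, 28.0% and 36.3% had such reads. Other cells of the plate thus held reads of both genes. Both were picked for low values in the 13 cells, so whether those values are more than few cells was not tested. Gzmb was at -6.97, with -8.80 against mouse 1 and -5.14 against mouse 2; its reads on the plate came from 2 of 13 cells. Kptn (-4.01), Sccpdh (-3.79), Abhd6 (-3.59), Mturn (-3.51), Trat1 (-3.43) and Fastkd2 (-3.34) were lower too; Mturn and Fastkd2 turned positive under 2 other settings.

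The stand-in draws held cells of the 2 BAL mice alone and carried no spread between day 10 plates, so their ranges are descriptions and not a test. Of the 50 draws, 1 each reached the difference of Ctsw, Rnase4, Pea15a and Trat1 and 3 that of Ctla2b. Among list members, 14 reached that of Il6, 4 that of Il10 and 2 that of Lipa. None reached the difference of the other genes given here. Such genes also arise by chance. With the scaling used, of all 7553 genes, 124 higher and 274 lower lay beyond every draw, while a draw set against the other draws gave a median of 81 higher and 145.5 lower (at most 171 and 188). As many as 124 higher genes were found in 7 of the 50 draws, and as many as 274 lower genes in 0.

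By list, the median log2 difference of 12 residency genes was 1.31 (-0.37 to 0.61 over the 50 draws), of 5 co-inhibitory receptors -1.63 (-1.26 to 3.25) and of 16 Treg-associated genes -1.06 (-0.34 to 1.75). For 29 oxidative phosphorylation genes it was -0.179 (-0.173 to 0.262). Th2 cytokines were at 2.75 (7 genes, reached by 2 draws), glycolysis genes at -0.58 (13 genes, 2 draws), interferon-stimulated genes at -0.23 (28 genes, 9 draws) and cell cycle genes at -0.87 (14 genes, 13 draws). Lipid genes were at 0.31 (24 genes, 13 draws), Th2 receptors at 0.17 (18 genes, 14 draws) and immediate early genes at -0.09 (11 genes, 17 draws). Cytotoxic genes were at 0.18 (10 genes, 25 draws) and antigen-presenting cell genes at 0.07 (3 genes, 30 draws). The mean of the cytotoxic genes was -0.63, so the sign for this list depends on the summary used. The lists of Th2 genes hold genes that the study discusses and are not independent evidence. Reads of the myeloid genes were found in 2 of the 13 plate cells (15.4%).

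In the clustering used, the day 10 plate held mainly naive and Treg-type cells. The numbers of cells per sort that the design lists set the make-up of this plate, so its shares estimate no tissue frequency. Naive or central memory cells were 21.2% of its 358 kept cells, compound Treg and interferon cells 17.6%, Treg-like cells 17.3%, interferon-responding cells 15.4% and compound Treg and naive cells 10.9%. Tfh-like cells were 7.26%, Th1-like cells 4.19% and Th2-like cells 3.63% (13 cells, exact 95% interval 1.95% to 6.13%). Over the 8 other clusterings the naive share ran from 18.4% to 30.5%, the Treg-like share from 4.19% to 45.8% and the Th2-like share from 0.28% to 8.66%. The compound Treg and interferon class was 6.03% to 19.6% in the 5 of them where it formed. Over the kept cells of all 3 plates, the naive cluster held the lymph node homing receptor gene Ccr7, a panel gene, in 85.6% of its cells against 9.6% of the others. Between the 13 Th2-like cells and the 336 cells of the other named T helper classes, 2513 genes reached the minimum, and the 8 largest folds among those with reads in both were all lower in Th2-like cells; 11 genes at 0 in either group were left out. They were Iigp1 (log2 fold -10.93), Gpr18 (-10.10), Gimap7 (-10.09), the lysosomal acid lipase gene Lipa (-8.10), Pdlim1 (-7.61), Igbp1 (-7.48), Atp6ap2 (-6.76) and Pdk1 (-6.60). With recovered reads the folds of Lipa (-9.34), Pdlim1 (-8.85), Igbp1 (-7.99) and Pdk1 (-7.40) were larger in size. Those of Iigp1 (-10.19), Gpr18 (-9.49), Gimap7 (-9.50) and Atp6ap2 (-6.24) were smaller. Each had reads in 1 or 2 of the 13 cells and in 75 to 152 of the 336, and with 1 plate there was no test. The shares of cells with reads were, for example, 7.7% against 22.3% for Gpr18 and 7.7% against 45.2% for Lipa. With only 13 cells in 1 group, a ranking by fold favours genes that few of those cells hold. The shared direction and the size of these folds are therefore no finding about the class.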

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

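All tests of this part were chosen only after the result was seen. Xist, which is transcribed from the inactive X chromosome of females, had reads in 52 of the 358 kept wells of the day 10 plate, in 0 of 320 wells of BAL mouse 1 and in 1 of 367 of BAL mouse 2. It is a signal outside the compared genes. Y-linked genes had reads in 205, 282 and 206 wells of BAL mouse 1, BAL mouse 2 and the day 10 plate. A cluster of 22 cells lay outside the T cell classes, 17 of them in BAL mouse 1, 1 in BAL mouse 2 and 4 on the day 10 plate. It carried the myeloid genes Lyz2 (27.3% of its cells against 3.5%) and Csf1r (18.2% against 1.0%), both of the marker panel that gave it its name. No myeloid class formed at resolution 0.6 or with the 2000 most variable genes. None formed with the deeper wells or with cells thinned before clustering either.

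On the day 10 plate, Y-linked reads were found in 3.8% of the wells with Xist (2 of 52) and in 66.7% of those without (204 of 306; Fisher exact p = 6.04e-19). Fewer reads in the wells with Xist are argued against: after thinning to 50000 reads, 62.1% of the wells without Xist still held a Y-linked read against 1 of the 52 with it (Fisher exact p = 3.46e-18), and median reads were 307756 and 320696. Cells of mice of both sexes in different wells would give such a split, but the 3.8% is the split itself and did not test this explanation, which stays open. The design names a mouse without allergen beside the exposed ones. Of the wells with Xist, 51 lay in plate columns from 18 on, and 195 of the 206 wells with Y-linked reads lay before column 18, a boundary picked from the data (permutation test of the mean column, p = 1e-05, the smallest that 100000 permutations can give, and adjusted p = 6.33e-05 over 19 tests, for each). The labels give the sex of no animal and the sort of no well, so the source of these wells was not settled.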

How the results depend on the processing

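The tests with recovered reads, wells in another order, clusters without the interferon markers, cells with a read of 8 myeloid genes left out, and equal numbers of cells were chosen after the result was seen. Median-ratio scaling moved the median log2 fold change of all genes from 0.10 to 0.05 (Th2-like), 0.01 to 0.05 (Treg-like), 0.04 to 0.03 (Th1-like) and 0.08 to 0.01 (BAL against day 10), and it kept 8 of 9 higher and 11 of 11 lower Th2-like calls. No named gene of the 3 class comparisons changed sign under any setting with a test. Leaving out a mouse gives values with no test. All named genes with a value then kept their sign. Plac8, Trat1, Tmem176a and Slamf6 (Th2-like), Cpne7, Sema4a, Btla and Ehd3 (Treg-like), Gimap6, Ramp1 and Capg (Th1-like) and Gzmb, Abhd6 and Gpr183 (day 10) moved by more than 1 moderated SD between mice, a limit that replaced 2 SE after the values were seen. Against day 10 a gene then needed the minimum RPKM in both remaining means, which gave values for 10 and 7 of 20 genes.

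Without a replicate block, 4 genes were higher and 7 lower in Th2-like cells, 15 and 11 in Treg-like cells, and 2 higher in Th1-like cells; 11 of 17, 9 of 12 and 6 of 9 named genes kept their calls. With no filter on low values the counts were 26 and 3 (Th2-like), 9 and 0 (Treg-like), 3 and 2 (Th1-like), and 0 and 0 (BAL against day 10); at an unadjusted p under 0.05 limma gave 1044 Treg-like genes and 1521 against day 10. With wells of 100000 reads and 1500 genes there were 4 higher for the Th2-like class, 2 and 4 for the Treg-like class, 20 lower for the Th1-like class, and 4 and 0 against day 10 (805 at an unadjusted p under 0.05). With cells thinned to 50000 reads there were 18 higher (Th2-like) and 164 lower (day 10). A pseudocount of 0.1 gave 19 higher (Treg-like), 3 higher (Th1-like) and 180 lower (day 10), and median-ratio scaling 124 lower (day 10). At resolution 0.6 the counts were 3 and 5 (Th2-like) and 5 and 4 (Treg-like), and at 1.6 they were 20 and 15 (Treg-like) and 14 and 38 (Th1-like). Clusters from the 2000 most variable genes gave 1 higher (Th2-like) and 0 and 0 (Treg-like; 582 at an unadjusted p under 0.05). With each plate clustered on its own they were 17 and 19 (Th2-like), 10 and 12 (Treg-like), 2 lower (Th1-like), and 137 and 11 (day 10). Pooling the other cells gave 37 and 34 (Th2-like) and 12 and 23 (Th1-like). Recovered reads gave 1 and 6 (Th2-like), 4 and 3 (Treg-like), 1 and 4 (Th1-like) and 101 lower (day 10). Wells in another order gave 5 higher (Th2-like) and 9 and 5 (Treg-like). Without cells with myeloid reads there were 17 lower (Treg-like) and 178 lower (day 10), and equal numbers of cells gave 2 and 0 (day 10), where fewer cells are the alternative's own construction.

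Among named genes, signs reversed only against day 10, for Mturn (2.80) and Fastkd2 (1.01) with wells of 100000 reads and 1500 genes, and for Mturn (3.12) and Fastkd2 (0.67) with each plate clustered on its own. With the deeper wells the shares of mouse 1 were 10.89% (Th2-like), 18.32% (Treg-like) and 0.99% (interferon-responding), and of mouse 2 12.81% (Th2-like) and 20.61% (Treg-like), while 15 and 40 cells with Treg markers stayed unnamed. The 2000 most variable genes gave Th2-like shares of 28.12% and 13.62%. Each plate on its own, where a further 34 cells with Treg markers stayed unnamed, gave 15.94% Treg-like and 0.0% interferon-responding cells in mouse 1. In mouse 2, resolution 0.6 gave 36.51% Treg-like cells, resolution 1.6 gave 9.81% Th1-like and 5.99% interferon-responding cells beside 22 cells (5.99%) of a compound Th1 and interferon class that the clustering used did not have, and another order of wells gave 10.35% Th1-like and 34.6% Treg-like cells. The Tfh-like share, 14.06% and 12.81% in mice 1 and 2, was 6.56% and 7.9% at resolution 0.6, 6.56% and 7.63% at 1.6, 3.44% and 0.0% with the 2000 most variable genes and 0.0% and 0.0% with each plate on its own. It was 7.43% and 8.08% with the deeper wells, 6.88% and 8.17% with cells thinned before clustering, and 7.19% and 8.17% with another order of wells. Of 19 list calls, 3 held with an estimated correlation. Among them were the Th2 cytokines of Th2-like cells and the Treg-associated genes of Treg-like cells. Each of these classes was formed on markers of its own kind. Of these 3, the interferon-stimulated list of Treg-like cells had an adjusted p of 0.185 with an estimated correlation when clustered without the interferon markers, where 84 cells with Treg markers stayed unnamed. It was 0.236 with these cells named Treg-like, a test also chosen after the result was seen. With the preset correlation the adjusted p was 7.31e-09 and 3.19e-07, and over 32 genes the median log2 fold change was 0.61 and 0.71 against 0.87, while the estimated correlation was 0.105 and 0.179 against 0.028. Except as said, the cause was not tested.

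No Th1-like class formed at resolution 0.6 or with the 2000 most variable genes, and the latter left 1 Th2-like cell on the day 10 plate, so these gave no value. No BAL cell was Tfh-like with each plate clustered on its own. Against day 10, no filter ended the calls of all 20 named genes and the deeper wells those of 18 of 19. Not run were the count tests (edgeR quasi-likelihood with TMM or RLE factors and filterByExpr, and the DESeq2 Wald test), since the deposited unit is RPKM, the interferon-responding and naive comparisons, and the mean of per-cell CPM for the classes of day 10. Depth was lowest in BAL mouse 1, with a median of 115174 reads per kept cell. With cells thinned to 50000 reads and the classes unchanged, the named genes of the class comparisons kept their calls (17 Th2-like, 12 Treg-like and 9 Th1-like).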

Other observations

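In this part, the genes described for the Tfh-like and unnamed classes, the list medians of the small classes, the plate column tests, the counts of stand-in calls by direction, and the thinning test of interferon-responding cells were chosen only after the result was seen. The tests of all calls with stand-in cells and of the shift of interferon-stimulated genes were written before. A cluster with no class name was led by Tmem176b, Tmem176a and Tdrp. It held 38 cells of BAL mouse 1, 28 of BAL mouse 2 and 5 of the day 10 plate. Genes of recirculating T cells were detected in it as well: S1pr1, the egress receptor, in 94.4% against 57.1% of other cells, Klf2 in 77.5% against 36.9% and Tcf7 in 84.5% against 58.6%. Ccr6, a chemokine receptor of Th17 cells, was found in 23.9% against 10.1%. S1pr1, Klf2, Tcf7 and Ccr6 belong to the marker panel on which the clusters were formed. Their percentages, over the kept cells of all 3 plates, thus describe the cluster and are no independent evidence. Against the mean of the other 4 BAL classes, the log2 difference in mice 1 and 2 was 4.62 and 3.38 for Tdrp, 3.63 and 2.93 for the homing receptor gene Gpr15, and 3.38 and 2.46 for Tmem176b. Fgl2 was lower, at -2.93 and -2.27. In Tfh-like cells, Xrcc4 was at 3.03 and 2.14, and Gbp2 and Ltb4r1 were lower, at -1.90 and -2.36 and at -1.67 and -2.16. No test was run on these differences.

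All 33 measured interferon-stimulated genes outside the panel were higher in interferon-responding cells than in other T cells, with a median log2 difference of 2.44 in BAL mouse 1 (8 cells) and 1.55 in BAL mouse 2 (43 cells). Both medians lay at percentile 100 of 10000 lists of equal size and like level drawn at random. The class was formed on interferon markers of the panel, so a rise of other interferon-stimulated genes was to be found. A gene also counted as measured when either group alone reached the minimum level. These values therefore describe the class and are no independent evidence. The cell cycle list had medians of 1.71 and 0.38 in the same cells (percentiles 100 and 80.5), and the cytotoxic list 0.40 and -0.05 (percentiles 95.3 and 20.1). In the 7 naive or central memory cells of each mouse, residency genes had medians of -0.59 and -0.31 (percentiles 0.2 and 2.0), co-inhibitory receptors -1.31 and -4.82 (percentiles 12.9 and 0.0), and cell cycle genes -3.11 and 0.06 (percentiles 50.0 and 98.2). Cells of any Treg type were 25.3% of BAL mouse 1, 31.6% of BAL mouse 2 and 45.8% of the day 10 plate. The last share depends on the sorts placed on the plate and is no tissue frequency to set against BAL. On that plate, compound Treg and naive cells, naive cells and Tfh-like cells were unevenly spread over the columns (permutation test of the mean column, adjusted p = 6.33e-05, 0.000304 and 9.5e-05). In contrast, the lowest adjusted p of the BAL classes was 0.446.

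Interferon-responding cells were 2.5% of BAL mouse 1 and 11.7% of BAL mouse 2. Sequencing depth of the plates is argued against as the whole cause, since after thinning every cell to 50000 reads the share of mouse 2 was 10.63% against 3.44% in mouse 1. A shift of interferon-stimulated genes in all cells of the plate may contribute: outside the interferon-responding classes 26 of 31 such genes were higher in mouse 2, with a median log2 difference of 0.453, while 95% of lists drawn at random gave -0.21 to 0.242. Whether that shift lies in the animal or in its plate cannot be separated with 1 plate per mouse, and no biological explanation was tested.

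The 1310 calls between Th2-like cells of BAL and of the day 10 plate may reflect few cells on the plate, since 19 of 50 draws of 13 BAL cells standing in for it gave as many. This held for the 1000 genes higher in BAL, whose number 28 of the draws reached. For the 310 lower genes, few cells on the plate were not excluded: 1 of the 50 draws reached their number with the scaling used, but 13 reached the 124 of median-ratio scaling and 3 the 180 of a pseudocount of 0.1. Day, organ, plate and sort stay as untested explanations.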
